A study of Mus musculus with 12 samples.

How the data were processed

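RNA from the frontal cortex of male C57BL/6 mice was measured in 12 libraries, 6 from Adar2-/- Gria2R/R mice and 6 from Adar2+/+ Gria2R/R litter mates. RNA was extracted with Trizol, and libraries were made with a stranded total RNA kit after bead removal of ribosomal RNA, per the labels. The submitters' processing notes name TopHat2 2.0.6, Bowtie2 2.02.0, HTSeq, DESeq, SAMtools 01.19.0 and the mouse build mm9, without their roles or order. The label of each library was taken from its genotype field. The labels give no litter, batch or sequencing date, and no statement on whether each library came from its own mouse beyond the 6 cortices of each genotype.

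The 3 deposited tables hold the authors' own comparisons between genotypes, with no value per library. The gene table lists 15191 genes with a mean normalized read count over both conditions, a signal in the form that DESeq writes, per the file headers. It also gives the deposited ratio of condition B over condition A, its log2 value, a p-value and an adjusted p-value from the authors. The exon table lists 156805 exon bins with a deposited mean normalized count, the authors' log2 ratio of control over Adar2, a p-value, an adjusted p-value and a dispersion, which is a score of the bin's spread in the count model, per the file headers. Its columns have the form that DEXSeq writes, but the program and its version are not given in the sources used here. The editing table lists 143 sites with the deposited percent of edited reads in control and in Adar2 libraries, an adjusted p-value from the authors, a site class and a position on mm9, another kind of deposited value that was used only to locate sites. The site caller, the test behind the adjusted p, the coverage of each site and whether libraries were pooled are not given in the sources used here.

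Depth per library and per editing site is therefore unknown, and no SD, confidence interval or count of libraries showing a direction could be computed. The lowest mean count of a listed gene was 15.01 and that of a listed exon bin was 20.0. The deposited adjusted p-values were made over more tests than the rows listed: the smallest gene p, taken as rank 1, and its adjusted p imply 25289 gene tests. The p of 2 bins was printed as 0, so the smallest bin p above 0, shared by the next 2 listed bins and taken as rank 4, was used, and it implies 246667 bin tests. With these ranks, the same arithmetic places 3 genes ahead of Cdh13 and 3 bins ahead of the Vps52 bin that were not analysed here. Spreadsheet dates stood in place of 22 gene names in the gene table and of 1 in the editing table, and these were left as listed.

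The gene table heads its conditions only A and B, and its 2 columns of means per condition were not used, since their headers name no genotype. Differences of genes and gene lists are therefore given as A over B, with no genotype attached. The exon table, whose header names control over Adar2, was set against the gene table in 10 forms of a correlation across genes without Adarb1. The rank correlation of B over A with control over Adar2, the sign expected with A as the knockout, was above 0 in all 10 forms. The permutation p was under 0.05 in 7 of them and the p adjusted over the 10 forms in 5. Across all 10709 genes rho was 0.038 (adjusted p = 0.003), and 50.7% of genes had the same sign in both tables. This was not taken to name the conditions, since bin values describe usage within a gene and need not carry the change of the whole gene: for Cdh13 the gene table had a log2 ratio of B over A of -0.47, where the count-weighted mean of its bins was 0.014. For Adarb1 the values were 2.21 and 0.241. The exon and editing tables name their genotypes themselves.

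The tests fixed before the data were examined needed counts or percentages per library and could not be run. These were a quasi-likelihood count test for genes, an exon usage test on bin counts, an exact permutation test per site, and a gene set test on log counts. In their place the deposited p-values were used with an adjusted p under 0.05. Sites and genes were counted by class and compared with Fisher's exact test, two-sided. The 26 gene lists were fixed before the data were examined. They were tested with the pre-ranked form of camera in limma 3.58.1 on a signed z made from each deposited p, with a preset correlation between genes of 0.01, and adjusted by Benjamini-Hochberg over the 25 lists with at least 4 measured members. No member of the list of mitochondrially encoded genes was measured. The correlation could not be estimated without values per library, so 0.05 and 0.1 were tried instead. The median of the genes hosting a site that fell was placed among 10000 random gene lists matched on mean count in 20 bins.

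Named genes followed a rule fixed before the data were examined. Adarb1, Adar, Adarb2 and Gria2 were always named, and since fewer than 20 genes passed, the 20 genes with the smallest p were named with them. The rule further took any list member that passed, the 2 most abundant members of each list, the bins of Adarb1, the bin with the smallest p in each of the 10 genes with the smallest Simes p, the sites that passed, and the 10 most edited sites that did not. Most of these are given as counts, and some items the rule names are not reported here. Other genes in the text were chosen after their values were seen.

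The adjustment by Benjamini-Hochberg and the list test were each tried on simulated z values for 15191 genes over 100 rounds. With the adjustment alone, of 200 genes shifted by 6 in z, 99.6% were recovered, with 4.9% false calls. In the list test the following was found. A list shifted by 1.5 was called in 98% of rounds, and lists without a shift had p under 0.05 in 3.3%. The simulation drew independent genes with uniform p-values where unshifted. The deposited p-values differ from that, with 1.86% of genes under 0.05.

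Gene symbols for 12642 of the 13536 identifiers in the exon table came from a gene name table. The order of genes along chromosomes came from a RefSeq table of GRCm38, which placed 14479 listed genes and was used only for neighbourhood, since the deposited positions are on mm9. Alternatives were other adjustments, thresholds, count minimums, correlations and statistics. Computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1, matplotlib 3.10.9 and R 4.3.3.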

Results

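RNA editing, gene expression and exon usage were compared in the frontal cortex of 6 male Adar2-/- mice and 6 Adar2+/+ litter mates. ADAR2, encoded by Adarb1, deaminates adenosine to inosine in double-stranded RNA, and inosine is read as guanosine. Mice of both genotypes carried the Gria2R allele, in which the genome itself encodes arginine at the glutamine-to-arginine site of this AMPA receptor subunit. The values were the authors' group means, percentages and p-values. The spread between libraries and their depth enter only as far as the authors' p-values took them up, and no SD per group is given.

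The first comparison was of mRNA levels. In the authors' deposited table, Adarb1 was 4.62-fold lower in condition A than in condition B (log2 difference -2.21, adjusted p = 3.06e-126), with a mean normalized count of 4181.0 over both conditions. Cdh13, which encodes a cadherin anchored to the membrane by a lipid, was 1.38-fold higher in condition A in the authors' deposited table (log2 difference 0.47, adjusted p = 0.0156), opposite to Adarb1. They were among the 3 of 15191 listed genes with an adjusted p under 0.05, 2 lower and 1 higher in A. Of the other 7 measured editing enzymes none passed, and in the authors' deposited table their log2 differences ranged from -0.20 for Adat1 to 0.38 for Apobec3, with 0.02 for Adar and 0.08 for Adarb2. Gria2 was at -0.01 in the authors' deposited table.

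The gene table heads its conditions only A and B, and its header does not say which is the knockout. The level of Adarb1 was not used to name them. All log2 differences of genes and gene lists are therefore given as A over B, with no genotype attached to their direction.

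The next genes by p missed the threshold. In the authors' deposited table, Gm14740 had a log2 difference of -0.98 and Slc17a8, which encodes a vesicular glutamate transporter, had one of -1.08, both with an adjusted p of 0.0596. Npy, the gene of neuropeptide Y, was at 0.32 with an adjusted p of 0.199 in the authors' deposited table. Among the other genes with the 20 smallest p-values, the authors' deposited table gave positive log2 differences for Hddc3 (0.85), Mt1 (0.33), Pdyn (0.33), Myl1 (1.33), Ifit3 (0.39), Col6a1 (0.56), Plcl1 (0.40), Fam129a (0.50) and Glra3 (0.31). It gave negative ones for BC061194 (-0.55), Rspo1 (-0.69), Tdg (-0.37) and Gpr133 (-0.52), and the adjusted p in the authors' deposited table was above 0.1 for each of them. Of all listed genes, 13915 (91.6%) differed by less than 1.2-fold between the conditions. An unadjusted p under 0.05 was found for 283 genes (1.86%) in the authors' deposited table, 128 higher and 155 lower in A, where uniform p-values would give 760.

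Editing was compared at 143 sites in 95 genes. In the authors' deposited table, 56 sites fell in the knockout, 13 rose and 74 did not pass. Of the 74, 5 were listed at 98% or more in both genotypes in the authors' deposited table, and whether these are edited was not tested. Of the 22 sites listed with an amino acid change, 19 fell, none rose, and 3 sites in Sfi1 did not pass. The amino acid labels, among them S/R for an Sfi1 site, were taken as listed, and whether the Sfi1 sites are edited was not tested. The median over these 22 sites in the authors' deposited table was 47.4% in the control and 11.6% in the knockout.

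Several of the sites that fell lie in ion channel subunits. The kainate receptor gene Grik2 fell at 3 sites in the authors' deposited table: Y/C (chromosome 10, position 48992582 on mm9) from 81.3% to 1.97%, I/V (position 48992595) from 71.5% to 28.1%, and Q/R (position 48964136) from 88.4% to 34.95%. The R/G sites of the AMPA receptor genes differed in size in the authors' deposited table. Gria2 (chromosome 3, position 80496208) fell from 73.0% to 23.2% and Gria4 (chromosome 9, position 4456006) fell from 79.5% to 23.4% in the authors' deposited table, while Gria3 (chromosome X, position 39007429) fell from 94.2% to 81.2%. The I/M site of the GABA-A receptor gene Gabra3 (chromosome X, position 69690631) fell from 96.2% to 19.1% in the authors' deposited table. The I/V site of the potassium channel gene Kcna1 fell from 30.4% to 1.40% in the authors' deposited table, and the I/M and Y/C sites of the calcium channel gene Cacna1d fell from 37.6% and 19.2% to values listed as 0.

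Sites in genes of the cytoskeleton and other functions fell as well. The K/E site of Cyfip2, which encodes a subunit of the WAVE actin regulatory complex, fell from 79.6% to 12.2% in the authors' deposited table (chromosome 11, position 46086145). The Q/R site of the filamin gene Flna fell from 41.7% to 1.96% in the authors' deposited table. The authors' deposited table gave falls from 76.1% to 25.8% for Tmem63b, from 33.0% to 1.38% for Son, from 27.0% to 0.71% for Unc80, and from 25.0% to 1.10% for Nova1. Cadps fell from 27.3% to 11.1% and Cog3 from 26.5% to 9.13% in the authors' deposited table. The 3 Sfi1 sites stood at 51.2%, 43.6% and 36.8% in the control and at 43.9%, 29.4% and 31.0% in the knockout in the authors' deposited table, with adjusted p of 0.406, 0.0614 and 0.594.

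**Figure D1:**
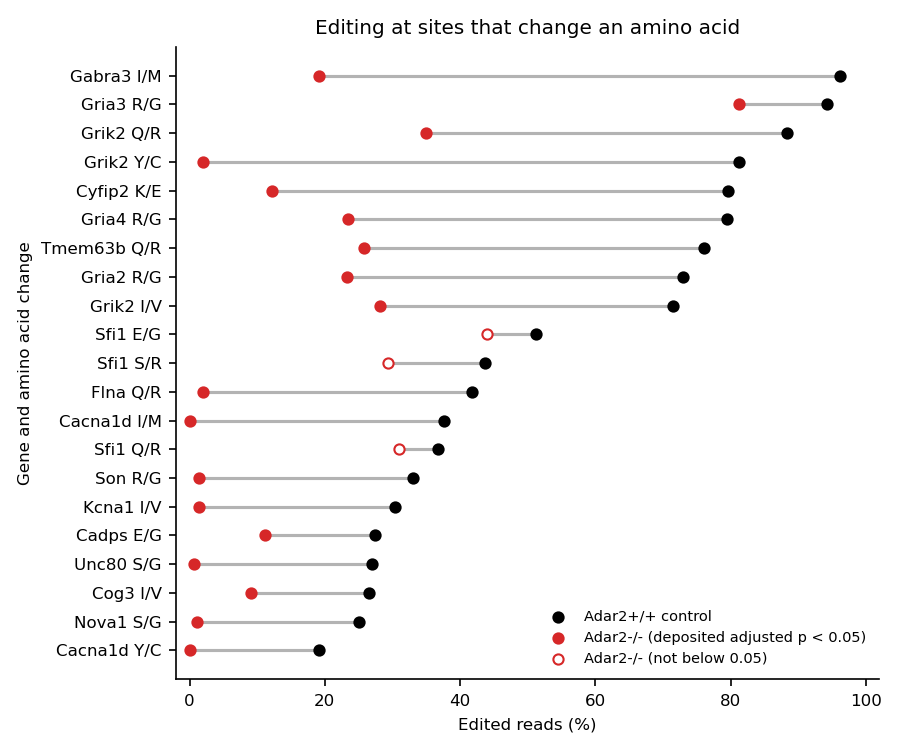
Percent of edited reads (horizontal axis) at 21 of the 22 sites that change an amino acid, with black points for the control and red points for the knockout, as group values from the authors' deposited table. Filled red points mark 18 sites that fell, and open red points mark the 3 Sfi1 sites that did not pass.

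Sites in 3' UTRs were more mixed. Of 100 sites in SINE repeats of 3' UTRs, in 62 genes, 28 fell, 12 rose and 60 did not pass in the authors' deposited table. Among those that fell, Snhg11 went from 79.7% to 3.52% (chromosome 2, position 158210689) and a Kif3c site from 70.0% to 6.93% (chromosome 12, position 3404248) in the authors' deposited table. Among those that rose, Ebna1bp2 went from 30.9% to 60% (chromosome 4, position 118298748) and Zfp324 from 9.76% to 35% (chromosome 7, position 13557536) in the authors' deposited table. Of 14 sites in 3' UTRs outside repeats, 9 fell and none rose. The 3 sites in 5' UTRs and the 2 synonymous sites did not pass, and of 2 microRNA sites Mir376c rose from 41.7% to 78.3% in the authors' deposited table.

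Amino acid sites fell more often than SINE sites, at 86.4% against 28.0% (Fisher's exact test, two-sided, p = 5.3e-07). Over all sites of each class, the median difference of knockout from control was -34.6 and -3.6 points. A fall was counted by the deposited adjusted p, which can depend on coverage. Coverage is unknown here, so the tests of this part may compare detection as well as change. Sites of one gene are not independent, and by genes the counts were 16 of 17 against 22 of 62 (Fisher's exact p = 1.37e-05). Sites in 3' UTRs outside repeats fell more often than SINE sites when counted by site (64.3% against 28.0%, Fisher's exact p = 0.0123), and by gene the counts were 7 of 10 against 22 of 62 (Fisher's exact p = 0.0781). These are 5 related tests, one of which left out Sfi1 (16 of 16 genes, Fisher's exact p = 1.29e-06). Sfi1 was the only amino acid gene without a fall, so leaving it out could only raise the share and adds no support.

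**Figure D2:**
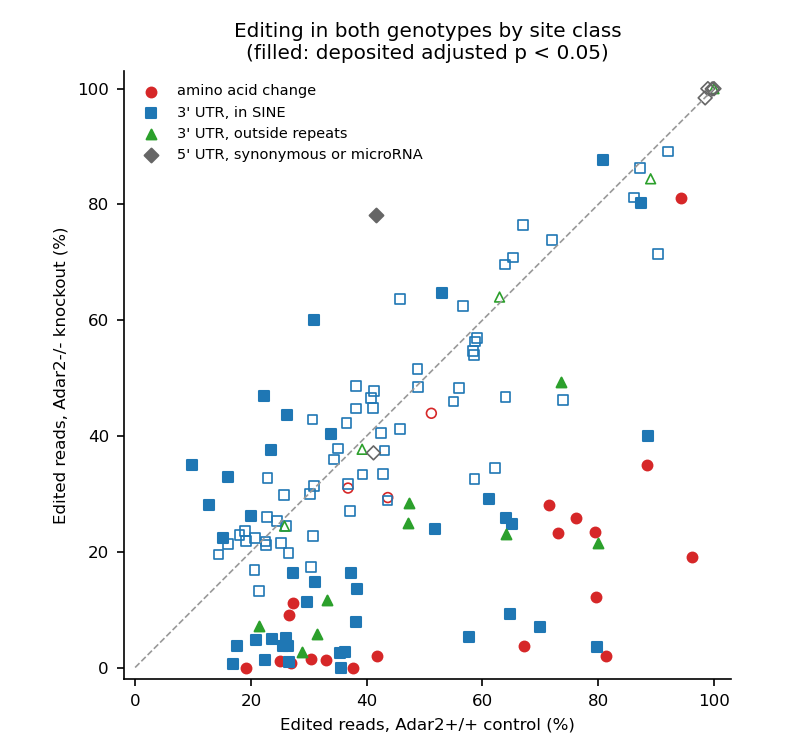
Percent of edited reads in the control (horizontal axis) and in the knockout (vertical axis) at 143 sites from the authors' deposited table, by site class, with the dashed line marking equal values and filled symbols marking the sites with a deposited adjusted p under 0.05. The 56 sites that fell lie below the line and the 13 that rose lie above it.

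Neighbouring sites in one gene could go different ways. Of 31 genes with at least 2 sites, 13 had a site that fell beside one that did not, and 6 had a site that fell beside one that rose. In the Ttbk2 3' UTR, the authors' deposited table listed a fall from 35.5% to 0 at position 120562688 of chromosome 2. At position 120562711 it gave 30.2% and 30.0% in the authors' deposited table, and at position 120562737 a rise from 12.8% to 28.2%. In Iws1, sites fell from 64.7% to 9.23% and from 64.1% to 25.8%, and another rose from 22.3% to 46.9%, in the authors' deposited table.

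Exon usage was compared over 149137 bins with a p-value. An adjusted p under 0.05 was found for 11 bins in 4 genes in the authors' deposited table, and 8 of them were in Adarb1. Of these, E009, E012 and E013 were lower in the knockout, with log2 changes of -5.23, -1.04 and -0.56 in the authors' deposited table. E015, E016, E017, E018 and E020 were higher, with log2 changes of 1.66, 1.62, 1.61, 1.64 and 1.88 in the authors' deposited table, and 10 of the 18 listed Adarb1 bins did not pass. Bin values describe usage within a gene, so a higher value need not mean more RNA of that bin in the knockout. The remaining bins were lower in the knockout: E022 of Hcfc2 (log2 change -0.80, adjusted p = 1.23e-10), E001 of Zfp941 (-0.93, adjusted p = 0.00102) and E024 of Vps52 (-0.72, adjusted p = 0.0349) in the authors' deposited table. With a mean count of at least 50 per bin and renewed adjustment, 6 bins passed, in Adarb1, Hcfc2 and Vps52. By a Simes p per gene, Vps52 had an adjusted p of 0.114. In all, 2489 bins (1.67%) had an unadjusted p under 0.05 in the authors' deposited table.

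The smallest-p bins of Zeb2 (E010, -0.54, adjusted p = 0.058) and Tdg (E024, -0.34, adjusted p = 0.0619) missed the threshold in the authors' deposited table, and passed when adjusted over the listed bins alone (adjusted p = 0.044 and 0.0461). Those of Rere, Sf3a2, Foxp2 and Glis2 had log2 changes of 1.0, -0.75, 0.36 and 0.29 in the authors' deposited table, with adjusted p of 0.394, 1, 1 and 1.

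**Figure D3:**
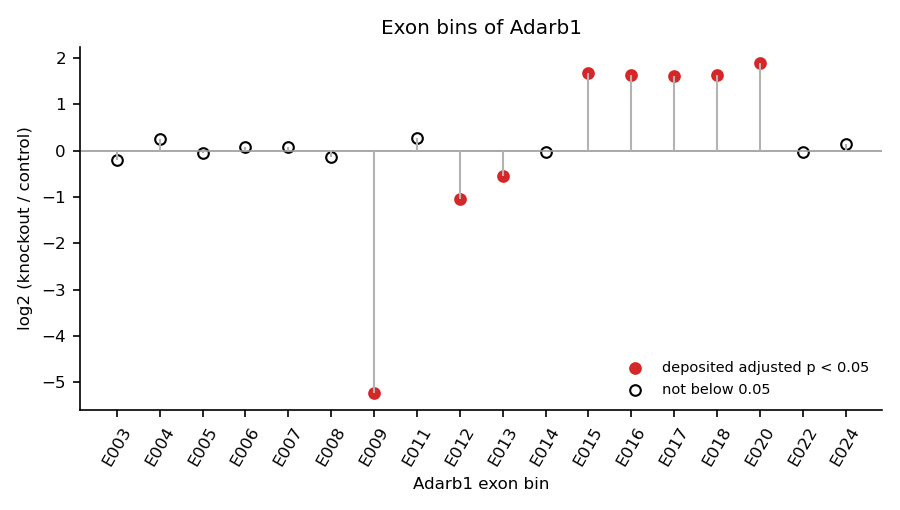
Log2 ratio of knockout over control (vertical axis) for the 18 listed exon bins of Adarb1 in order of bin number (horizontal axis), from the authors' deposited table. Filled points mark the 8 bins with an adjusted p under 0.05, from -5.23 at E009 to 1.88 at E020. The values describe usage within the gene and not its level.

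Genes hosting a site that fell were compared in the other tables. Of 45 such genes, 44 were in the gene table, and the level of 1 passed in the authors' deposited table. Cyfip2 had a log2 difference of -0.23 with p = 0.00223 and an adjusted p of 1 in the authors' deposited table. The median log2 difference of the 44 genes was 0.001, at the 41.0th percentile of 10000 random gene lists matched on mean count. Of 678 bins in 36 of these genes, 0 passed in the authors' deposited table and 16 had an unadjusted p under 0.05.

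Gene groups were compared through 25 lists fixed before the data were examined. Immediate early genes, transcribed after neuronal activity, were lower in condition A: 21 of 27 had a negative log2 difference, with a median of -0.15 (camera in limma, adjusted p = 2.69e-08). None passed over all genes and 2 passed when adjusted over the list alone, Dusp1 and Arc, with log2 differences of -0.38 and -0.54 in the authors' deposited table. Genes of the interferon response and double-stranded RNA sensing were higher in condition A: 22 of 27 were positive, with a median of 0.12 (camera in limma, adjusted p = 4.69e-05). None passed over all genes and 1 passed when adjusted over the list alone, Ifit3 at 0.39, while Oas1a and Ifit1 stood at 0.78 and 0.47 in the authors' deposited table. The deposited group values did not allow an estimated correlation. At a preset correlation of 0.1 the adjusted p of these 2 calls was 0.00492 and 0.0401 (camera in limma). Higher correlations were not tried. The list test takes genes as its units, so its p-values do not measure how list members vary together between mice.

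The list test also called microglia, striatal neuron and interneuron markers and ribosomal protein genes, but not under every alternative. Of 16 microglia markers 14 were positive, with a median of 0.12 (camera in limma, adjusted p = 2.98e-05, and 0.133 with the log2 difference as the statistic), and 0 passed over all genes or adjusted over the list alone. Of 11 striatal neuron markers 8 were positive, with a median of 0.18 (camera in limma, adjusted p = 7.78e-04, 0.0647 with the log2 difference as the statistic and 0.0574 rank-based). None of them passed over all genes and 2 passed when adjusted over the list alone, Pdyn and Ppp1r1b, at 0.33 and 0.30 in the authors' deposited table. Of 18 interneuron markers 12 were positive, with a median of 0.10 (camera in limma, adjusted p = 0.0235, and 0.128 at a correlation of 0.05), with 0 passing over all genes and 1 when adjusted over the list alone, Npy. Of 36 ribosomal protein genes 32 were positive, with a median of 0.03 (camera in limma, adjusted p = 0.0168, and 0.156 at a correlation of 0.05), and 0 passed over all genes or adjusted over the list alone. The editing enzymes were called lower in condition A (adjusted p = 3.63e-27 in limma), which rested on Adarb1: with it left out the adjusted p was 0.594. Of their 8 measured members 1 passed over all genes and 1 adjusted over the list alone.

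The other 18 lists did not pass the list test. Their adjusted p lay under 0.1 for neighbours of Adarb1 and astrocyte markers (0.0547 each), excitatory neuron markers (0.0597), and for mRNAs with known edited codons, ionotropic glutamate receptors, potassium and calcium channels and innate inflammation (0.0808 each). Among mRNAs with known edited codons, 1 of 35 passed over all genes and 2 adjusted over the list alone, Cyfip2 among them, with a median of 0.01 where the camera test pointed lower. Among neighbours of Adarb1, 0 of 28 passed over all genes and 1 adjusted over the list alone, Col6a1. For 16 lists, 0 members passed either over all genes or adjusted over the list alone. The median log2 difference was 0.07 for both ionotropic glutamate receptors and potassium and calcium channels, 0.15 for innate inflammation, 0.09 for excitatory neuron markers, 0.06 for astrocyte markers, and 0.04 for neighbours of Adarb1. It was 0.06 for synaptic vesicle genes (adjusted p = 0.176) and for circadian clock genes (0.369), -0.02 for neuronal splicing regulators (0.359), 0.13 for choroid plexus and ependyma markers (0.378), and 0.04 for oligodendrocyte precursor markers (0.435). It was -0.01 for oligodendrocyte markers (0.545), p53 targets and cell death (0.762), heat shock and the unfolded protein response (0.984), and endothelium and pericyte markers (0.992). GABA-A receptors had a median of 0 (0.721) and blood markers one of 0.04 with a mean of -0.36 (0.954).

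**Figure D4:**
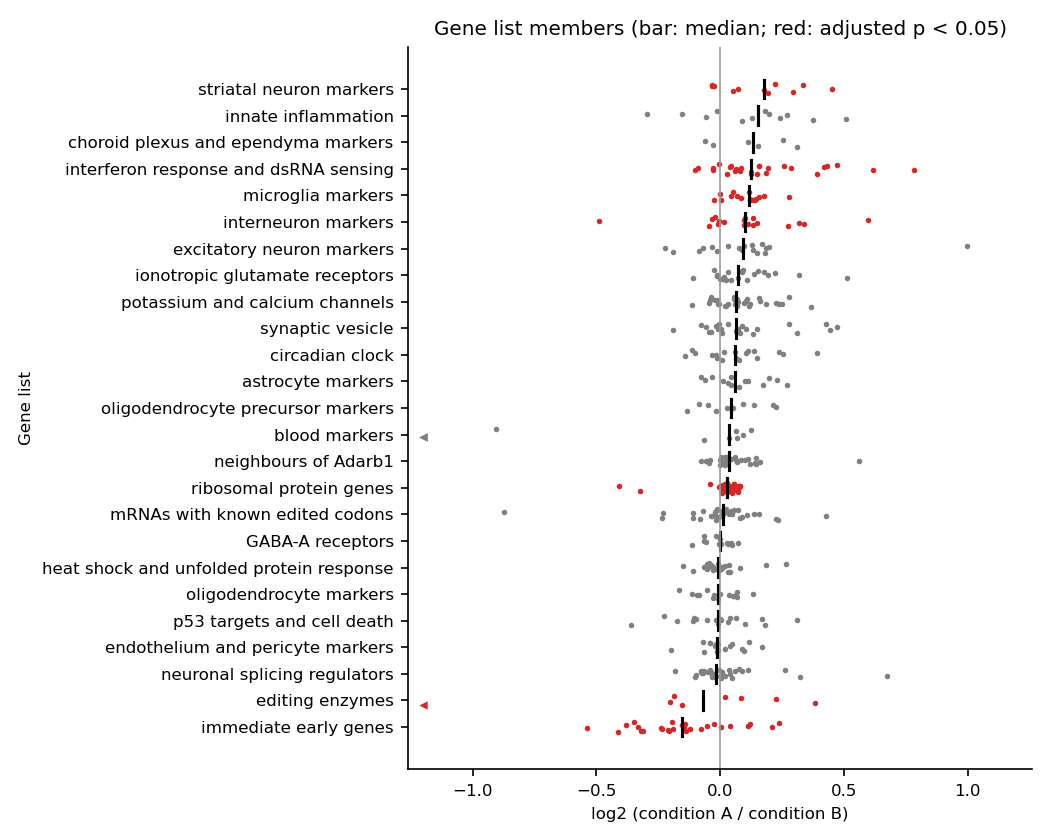
Log2 ratio of condition A over condition B (horizontal axis) for members of 25 gene lists (vertical axis), with a point per gene and a black bar at each median. Red marks the 7 lists with an adjusted p under 0.05, and arrowheads mark the 3 genes beyond the axis, Adarb1, S100a8 and S100a9.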

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

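All alternatives given here were chosen after the data were seen, since the planned ones needed values per library. Not run were other normalizations and test programs, count filters on libraries, a surrogate variable or library number as covariate, leaving out each of the 12 libraries, other exon usage and gene-level exon tests, transformed, rank, quasi-binomial or zero-recoded tests and coverage minimums for editing, and camera with an estimated correlation or fry. Other splits of the samples could not be counted for the same reason. No paired analysis was possible because the deposited tables hold no values per library, and the replicate numbers mark no litter.

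With an adjusted p under 0.1, 5 genes passed in place of 3. The other adjustments and a mean count of at least 100 gave 2 or 3. Of exon bins, 13 passed in place of 11 when adjusted over the listed bins alone, with the Zeb2 and Tdg bins added (adjusted p = 0.044 and 0.0461), 14 at an adjusted p under 0.1, and 10 by Bonferroni over the listed bins. With a mean count of at least 50, 6 passed, as several Adarb1 bins and the Zfp941 bin have lower counts, and with Adarb1 left out 3 did. The number of genes with a changed bin lay between 3 and 6, against 4. Changed editing sites numbered 53 to 64 under stricter thresholds or a minimum difference of 10 points, in place of 69. Leaving out the sites at 98% or more in both genotypes could not change the 69, as none of those sites had passed. At an adjusted p under 0.001, 50 had fallen and 3 had risen.

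Of the gene lists, 4 passed with the log2 difference as the statistic and 4 in the rank-based test, in place of 7, and the cause was not tested. At correlations of 0.05 and 0.1, 5 passed, among them the microglia and striatal lists. The immediate early and interferon lists passed in each of the 6 alternatives, none of which measured how list members vary together between mice. The interneuron list had adjusted p from 0.0028 to 0.306 and the ribosomal list from 0.000289 to 0.93. Blood markers passed only with the log2 difference as the statistic. Unknown depth at editing sites limits the reading of differences of a few points.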

Other observations

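All tests in this part were chosen after the data were seen, except the 2 on sites with more editing in the knockout, which were set before their results were seen.

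Several genes had large fold differences with large p-values. In the authors' deposited table, Lars2 had a log2 difference of condition A over B of -3.28 with p = 0.288. The muscle genes Ttn and Atp2a1 had log2 differences of -2.40 and -3.68, and the neutrophil genes Ngp and Ltf had -2.06 and -1.92, in the authors' deposited table, with p from 0.121 to 0.499. Other muscle genes varied in the authors' deposited table: Myh4, Myh2, Acta1 and Myh1 had -1.54, -0.49, -0.41 and -0.34, while Myl1 had 1.33 with p = 0.000261. The olfactory genes Omp and S100a5 had 0.86 and 1.51 in the authors' deposited table (p = 0.602 and 0.581). Of the 33 genes with an absolute log2 difference above 1, 25 had a p above 0.1 in the authors' deposited table. Editing was listed at 98% or more in both genotypes for 5 sites in the authors' deposited table. These may be variants against the reference genome and not edited, which was not tested. None of them passed, so leaving them out could not change the 69 changed sites.

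Small p-values lay near Adarb1 on chromosome 10: Col6a1, Tdg and Slc17a8 were 5, 132 and 178 listed genes away, and Hcfc2, with its exon usage call, 134. A segment of donor-strain chromosome carried with the targeted allele may account for them. With 200 genes on each side, p under 0.01 was found for 3 of 400 genes against 55 of 14078 elsewhere (Fisher's exact p = 0.22), and of 6 settings only p under 0.001 with 200 genes passed (Fisher's exact p = 0.0107), while none of 6 around Gria2 did. Genes with a bin at adjusted p under 0.1 were 2 of 314 in the window against 2 of 10355 elsewhere (Fisher's exact p = 0.005) but 0 of 157 with 100 genes on each side, and Zfp941 was not among the genes placed. The genes counted near Adarb1 in the tests that passed are those whose closeness raised the question. Those p-values therefore add no independent support for a cluster. An effect of losing ADAR2 cannot be told apart from such a segment, as both go with the genotype. That 0 of the 4 genes host a listed site that fell decides nothing, since these genes host no listed site at all. Other genes of chromosome 10 do host listed sites. In the authors' deposited table, sites fell in Grik2 and in Glt8d2 (position 82113524, from 26.64% to 0.9%), while those of Nt5dc3 and Tspan31 did not pass. How far these sites lie from the 4 genes was not determined.

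In the H2 region of chromosome 17, Rps18 had a log2 difference of -0.32 (p = 0.0519) and its near-identical copy Rps18-ps3, on chromosome 8, one of 1.56 (p = 0.00218) in the authors' deposited table. Their summed means had a ratio of 1.003 between the conditions, so reads moving between the copies, for instance through a strain variant, may account for both. A difference of ribosomal protein mRNA as a class in the direction of Rps18 is argued against by a median of 0.028 over the other 35 genes. The fullest window of 50 genes in the genome, from H2-Q2 to Tdrd6, held 8 genes with p under 0.05, and over the 6 settings tried as small a p came up in a share of 0.011 of shuffled gene orders, which argues against chance clustering of independent genes. Windows of 100 and 200 genes there had shuffle p of 0.059 and 0.091. With the p limit of 0.01 the fullest windows of 50, 100 and 200 genes lay on chromosome 8 instead (p of 0.045, 0.027 and 0.04 in a permutation test that shuffled gene order). All 3 held Cdh13, and the 2 larger ones also held Rps18-ps3. The 8 genes of the chromosome 17 window of 50 were H2-T24, H2-T22, H2-T10, H2-M5, Mut, Gpr111, Tnfrsf21 and Tdrd6, without Rps18. H2 genes can share reads, which would not account for the genes named there that are not H2 genes. Vps52, with its exon usage call, lies on chromosome 17 as well, and its distance from Rps18 was not determined. No biological explanation was tested for the region of chromosome 17 or that of chromosome 8.

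Of the 13 sites that rose, 6 lay in a gene with a site that fell, against 15 of 74 sites that did not pass (Fisher's exact p = 0.074). Access of the remaining enzyme to sites that ADAR2 no longer edits therefore stays open. The sites that rose had a lower control level, with a median of 23.6% against 41.2% (permutation p = 0.01), which is consistent with more room to rise. Error in the control percentages could give the same difference, and the coverage that would decide it is unknown. No test here separates these explanations.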
